A study of Mus musculus with 9 samples.

How the data were processed

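Gene expression was measured by bulk RNA sequencing of quadriceps muscle from C57BL/6 mice with a volumetric muscle loss injury, in which a block of muscle is cut out. The labels give 4 libraries as wild type and 5 as Il17ra-/-, a knockout of the receptor subunit for interleukin-17 cytokines, and this genotype label is the only factor that varies between samples. The labels disagree on the treatment and the time: the sample characteristics name saline and a harvest 1 week after surgery, while the extraction protocol names PCL and a collection 6 weeks after surgery. Neither version could be chosen from the sources used here, and no statement below depends on it. The series' design text speaks of 3 animals per genotype, while 4 and 5 libraries are labelled. It describes the replicates as animals, and no label ties a single library to an animal, a litter, a sequencing run or a day, so that any such batch cannot be separated from genotype.

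Per the labels' protocols, RNA was extracted with TRIzol and RNeasy columns, had an integrity number above 8.0, and was made into libraries with the TruSeq RNA v2 kit, which does not mark the strand, for sequencing at a stated depth of 30 M (mega) reads. Reads were aligned with STAR, per the submitters' processing notes; its version is not given in the sources used here. The deposited values are whole-number read counts per gene, made by the authors with featureCounts 1.6.0 per the file headers, over exons summed by gene, for read pairs, without strand, and with the GENCODE M21 mouse annotation (GRCm38). With these settings a read that maps to several places is not counted, and strand cannot assign reads where exons of genes on opposite strands overlap. All 55536 gene identifiers in the 9 files matched the GENCODE M21 annotation used here for names and coordinates, which are given 1-based on GRCm38.

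The libraries held 31.3 to 46.4 M counts, and a count of 3 in a library corresponded to 0.0646 to 0.0959 CPM, the library-scaled count. Genes with low counts were removed with the default filterByExpr rule, which left 16039 genes. Library sizes were scaled with TMM factors, and the groups were compared with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), two-sided, with genotype label as the only term and all 9 libraries in the fit. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Unless another test is named, adjusted p-values of genes come from this test. Log2 fold changes are labelled Il17ra-/- minus labelled wild type and are followed by their standard error (SE). The SE was taken as the absolute log2 fold change over the square root of the test's F value. The interval given for Il17ra assumes a normal distribution, which makes it too narrow with few libraries. CPM values are scaled with the TMM factors and given as mean ± SD.

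A total of 31 gene lists with 505 entries, of which 503 matched the annotation, were written from textbook knowledge before the data were examined. The 27 lists with at least 5 tested members were tested with limma 3.58.1 (camera on voom values, preset correlation of 0.01 between genes, Benjamini-Hochberg adjustment over the lists). Camera asks whether the test statistics of a list's genes are on average higher or lower than those of the other genes. Beside it stand camera with the correlation estimated from the data and the fry test. Cell type lists were also summarised per library as the mean of log2(CPM + 1) and compared, with the library measures, by two-sided exact permutation tests over the 126 ways to split 9 libraries into 4 and 5. The smallest two-sided p these can give is 0.0159. Calls within 10 Mb of Il17ra were compared with calls elsewhere by Fisher's exact test.

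Named genes follow a rule fixed before the data were examined: Il17ra; the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups did not overlap and whose mean was at least 1 CPM, leaving out gene models named only by a number and sex-linked genes; and up to 4 members of each list with the smallest p, whether or not they passed. A few genes that the rule names are not reported here. Genes outside this rule were chosen after their values were seen. In the report they are the most abundant genes (Gsn, Col3a1, Dcn, Fn1, Col1a2 and Col1a1) and the marker genes Ptprc, Pecam1, Myh4, Lyz2 and Cspg4. Fos, Egr1, Tspan11 and genes named as neighbours of another gene belong there too. In the closing part they are Eif4a1, Lyz2, Cd14, C1qb and C1qc where explanations are weighed, and the genes that the other observations say were chosen in this way.

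The procedure was tested on simulated counts with the means and library sizes of these libraries, for the comparison of the 4 against the 5 libraries over 15480 genes. It recovered 19.4% of genes changed 1.5-fold, 67.7% of those changed 2-fold and 76.6% of those changed 4-fold, and 6 of 112 calls were false. Alternatives were other scalings (RLE, upper quartile, library total only, and a total without mitochondrial and the 10 most abundant genes), DESeq2 1.42.0, limma-voom with and without quality weights, robust edgeR, other count filters and thresholds, 1 surrogate variable (sva 3.50.0), the replicate number as a block, and leaving out each library in turn. The figures were drawn with matplotlib.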

Results

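Quadriceps muscle of mice with a volumetric muscle loss injury was profiled by RNA sequencing in 4 libraries labelled wild type and 5 labelled Il17ra-/-, and the comparison asks how the transcriptome differs between libraries with these labels, which name a knockout of an interleukin-17 receptor subunit. Total counts ran from 31294089 to 46435401, with 35.3 ± 2.75 M (mega) counts (SD, n = 4) in the libraries labelled wild type and 41.6 ± 4.52 M counts (SD, n = 5) in those labelled Il17ra-/- (exact permutation p = 0.0635). The number of genes with a count ran from 17256 in wild-type replicate 2 to 20945 in wild-type replicate 1. Genes of connective tissue were the most abundant in the 9 libraries. Gsn, which encodes the actin-severing protein gelsolin, was the most abundant gene at a mean of 34681 CPM, followed by Col3a1, Dcn, Fn1, Col1a2 and Col1a1, all components of the extracellular matrix. Muscle transcripts were less abundant, with Acta1, the skeletal muscle actin, at 856 ± 298 CPM (n = 4) in the libraries labelled wild type and Myh4, a fast myosin, at 142 ± 40.3 CPM. Ptprc, the pan-leukocyte marker CD45, did not exceed 0.461 CPM in any library. The labels describe the samples as muscle and name no sort or depletion of cells; whether whole tissue was sequenced is not settled by the sources used here, so levels of cell type markers describe these libraries and not the tissue. Wild-type replicate 2 lay apart from the other 8 libraries on the first principal component, which held 34.3% of the variance, and Il17ra-/- replicate 1 on the second (17.4%), at 89.1 against −33.1 to 16.0 in the others.

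Il17ra, the targeted gene, was higher in the libraries labelled Il17ra-/-. The gene lies on chromosome 6 from 120463247 to 120487559 on the plus strand and has 13 annotated exons. It stood at 96.8 ± 19.7 CPM (n = 4) in the libraries labelled wild type and at 208 ± 43.2 CPM (n = 5) in those labelled Il17ra-/-. The log2 fold change was 1.11 (SE 0.17, approximate 95% confidence interval 0.78 to 1.43, edgeR adjusted p = 0.00208). The exact permutation p was 0.0159, the smallest this design can give. The groups did not overlap, since the libraries labelled wild type reached 119 CPM at most and those labelled Il17ra-/- started at 181 CPM. Between 2770 and 10491 counts stood behind each value. The level of the targeted gene therefore goes against a loss of its whole transcript in the libraries labelled Il17ra-/-. By itself it does not decide whether the labels are right, and every direction below refers to the labels as given. The counts are summed over all exons, of which the last holds 84.8% of the exon length, and the labels do not say which part of the gene the allele removes. Among the other members of the list of IL-17 ligands, receptors and adaptors, none of the 7 tested passed over all genes. Traf6, an adaptor of the receptor, had a log2 fold change of 0.47 (adjusted p = 0.121) and Traf3ip2, which encodes the adaptor Act1, one of 0.27 (adjusted p = 0.388).

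**Figure D1:**
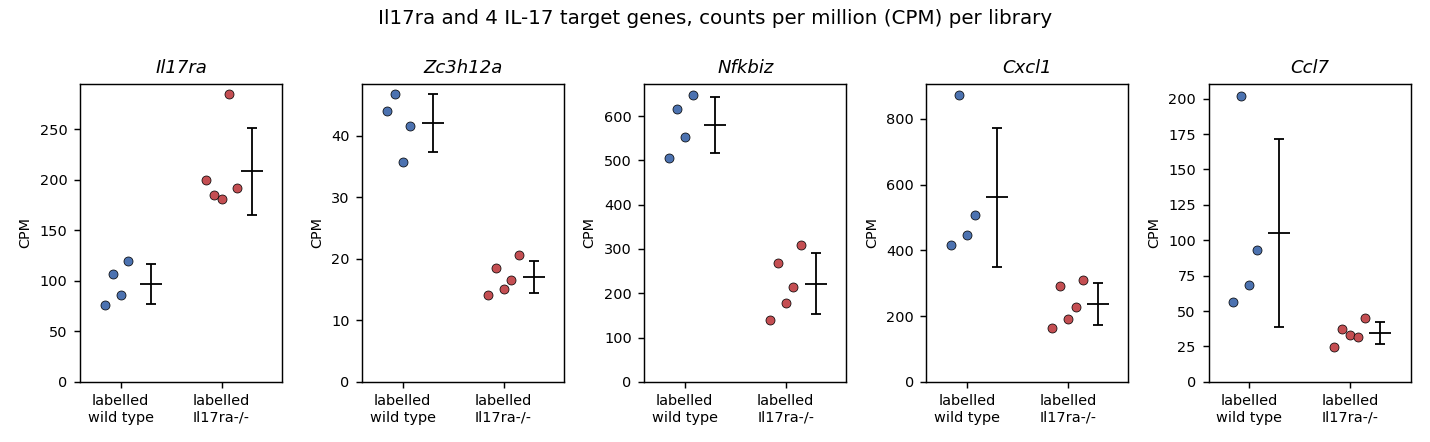
Library-scaled counts (CPM, y axes, from 0) of Il17ra and of 4 IL-17 target genes in each library (points), for 4 libraries labelled wild type (blue) and 5 labelled Il17ra-/- (red); the bar beside each group is its mean ± SD. Il17ra is higher and the 4 targets are lower in every library labelled Il17ra-/- than in any labelled wild type.

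Across the transcriptome, 6 genes of slow muscle fibres and 1 clock gene were among the 10 largest rises in the libraries labelled Il17ra-/-, and the 10 largest falls included genes induced by inflammation beside genes of low abundance. Nr1d1, the clock repressor REV-ERB alpha, rose from 15.5 ± 4.65 to 106 ± 10.4 CPM (log2 fold change 2.77, SE 0.18, adjusted p = 8.01e-06). Myh7, the slow myosin heavy chain, rose from 10.1 ± 8.15 to 85.0 ± 22.1 CPM (3.07, SE 0.45, adjusted p = 0.00177). Tnfaip6, a secreted hyaluronan-binding protein induced by inflammatory signals, fell from 777 ± 303 to 148 ± 52.2 CPM (−2.40, SE 0.27, adjusted p = 3.12e-04), and the chemokine gene Cxcl10 fell from 113 ± 57.4 to 21.6 ± 9.42 CPM (−2.38, SE 0.34, adjusted p = 0.00131). The orphan nuclear receptor gene Nr4a3 fell from 62.7 ± 11.2 to 10.01 ± 6.38 CPM (−2.65, SE 0.36, adjusted p = 9.18e-04). Besides Myh7, the slow fibre genes were Myl3, Tnnc1, Tnni1, Myl2 and Tnnt1, with log2 fold changes between 2.12 and 2.37. Myom3, a gene of the sarcomere M-band, rose by 2.00 on the log2 scale (SE 0.35, adjusted p = 0.00567). Mettl21c, a muscle methyltransferase gene, stood at 0.0623 ± 0.0730 CPM in the libraries labelled wild type and 2.59 ± 1.48 CPM in those labelled Il17ra-/-. Timp4, a metalloproteinase inhibitor gene with a log2 fold change of 2.09, was close to the threshold (adjusted p = 0.0488), and its call was lost under 13 of 21 alternatives.

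The remaining large falls were in genes of low abundance. Cd68, a lysosomal protein gene used as a macrophage marker, fell from 17.9 ± 5.20 to 2.58 ± 1.01 CPM (−2.80, SE 0.30, adjusted p = 2.17e-04), and its annotated start lies 783 bp downstream of Eif4a1 on the same strand. Nrros, a gene of myeloid cells, fell from 3.15 ± 0.973 to 0.412 ± 0.105 CPM, Fam107a from 3.36 ± 1.38 to 0.621 ± 0.313 CPM and Clec2e from 2.35 ± 1.11 to 0.451 ± 0.204 CPM. Milr1 stood at 2.99 ± 0.735 against 0.107 ± 0.155 CPM, Iqcn at 6.86 ± 4.23 against 0.333 ± 0.233 CPM and Tmem88 at 4.10 ± 4.23 against 0.337 ± 0.283 CPM. Values of Milr1, Iqcn and Tmem88 are uncertain. The annotated span of Milr1 overlaps that of Polg2 on the other strand by 542 bp. Iqcn and Tmem88 lie 2841 and 274 bp downstream of the more abundant genes Jund and Kdm6b on the same strand. Spans including introns also overlap on opposite strands for Nr1d1 with Thra, Myl3 with Pth1r, Tnnc1 with Nisch, Timp4 with Syn2 and Cxcl10 with Art3. Whether exons overlap in these pairs, so that counting without strand cannot separate them, was not examined. Of the overlapping partners Polg2, at a mean of 10.97 CPM against 1.39 CPM for Milr1, fell (−1.46, adjusted p = 3.86e-04), as did Pth1r (−0.56, adjusted p = 0.0334), and these others did not pass, with log2 fold changes of 0.20 for Thra, −0.09 for Nisch, −0.69 for Syn2 and 0.33 for Art3.

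In all, 491 of 16039 tested genes were called by edgeR's quasi-likelihood test, 217 higher and 274 lower in the libraries labelled Il17ra-/-, and 218 of them had an absolute log2 fold change of at least 1 (91 higher, 127 lower). The groups did not overlap for 474 of the 491, and for 9.18% of all tested genes against 1.59% by chance. The share of calls that were lower was 55.8%, and it was 41.3% when libraries were scaled by their totals alone. The count fell to 275 without Il17ra-/- replicate 3 and to 323 without Il17ra-/- replicate 1, and DESeq2 called 1026. Without wild-type replicate 2, 567 genes were called. Among the other genes named as called, the call was lost under 11 of 21 alternatives for Clec2e, 10 for Adipoq, 8 for Il6, 7 for Pmp22 and Tmem88, 6 for Acta1, Fbxo32 and Pfkm, 5 for Cxcl14 and Fam107a, 4 for Hic1 and Pi16, and 1 for Cxcl9 and Mettl21c.

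Of the genes with roles in slow muscle fibres, most rose. Of 14 tested slow fibre genes, 9 rose and none fell over all genes, and 9 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.03e-09; adjusted p = 0.136 with an estimated correlation). Examples are the slow regulatory light chain Myl2 (2.12), the ventricular and slow light chain Myl3 (2.37) and the slow troponins Tnnc1 (2.31) and Tnnt1 (2.12). Of 15 fast fibre genes, 2 rose over all genes and 4 adjusted over the list alone (camera adjusted p = 1.00e-05; adjusted p = 0.349 with an estimated correlation). These were Myh2, the myosin of fast oxidative fibres, from 57.9 ± 36.6 to 223 ± 42.5 CPM (1.95, SE 0.36, adjusted p = 0.00838), and Acta1, to 1643 ± 206 CPM (0.94, SE 0.21, adjusted p = 0.0289), while Myh1 (1.07, adjusted p = 0.0953) and Ckm, the muscle creatine kinase (0.63, adjusted p = 0.150), did not pass. Within libraries, the mean log2(CPM + 1) of the slow list minus that of the fast list was −2.45 ± 0.19 (n = 4) in the libraries labelled wild type and −1.74 ± 0.33 (n = 5) in those labelled Il17ra-/- (exact permutation p = 0.0317).

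A minority of the metabolic genes of muscle and fat passed, and those that did rose. Of 15 fatty acid oxidation genes, 3 rose, both over all genes and adjusted over the list alone (camera adjusted p = 2.28e-04; adjusted p = 0.343 with an estimated correlation): the fatty acid transporter Cd36 (0.89), the fatty acid binding protein Fabp3 (1.16) and Acsl1 (0.93). The calls of Acsl1 and Fabp3 were lost under 10 and 9 of 21 alternatives. The list of glycolysis and glycogen genes held 3 rises among 15 members, among them Gys1, the muscle glycogen synthase (1.09), and Pfkm, the muscle phosphofructokinase (0.65), with 6 rises and 2 falls adjusted over the list alone (camera adjusted p = 0.0110; adjusted p = 0.468 with an estimated correlation). No gene of the oxidative phosphorylation list passed over all genes and 4 of 19 rose adjusted over the list alone, although 17 had a positive log2 fold change (camera adjusted p = 3.80e-05; adjusted p = 0.281 with an estimated correlation). Its smallest p belonged to citrate synthase, Cs (0.33, adjusted p = 0.0775). Of 12 adipocyte genes, 2 rose over all genes and 8 adjusted over the list alone (camera adjusted p = 5.35e-06; adjusted p = 0.335 with an estimated correlation). These were Car3, carbonic anhydrase 3, which muscle also makes, from 56.7 ± 11.02 to 152 ± 34.7 CPM (1.42), and Adipoq, the adiponectin gene, from 1.36 ± 0.768 to 5.05 ± 2.80 CPM (1.89). The mean of the adipocyte list per library was 0.74 higher on the log2 scale in the libraries labelled Il17ra-/- (exact permutation p = 0.0317, adjusted p = 0.163).

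Some markers of muscle stem cells and of the cells that surround small vessels rose, though most genes of these lists did not pass. Of 17 tested genes of satellite cells and regenerating fibres, Pax7, the transcription factor of satellite cells, rose from 32.9 ± 7.46 to 62.7 ± 7.34 CPM (0.93, SE 0.15, adjusted p = 0.00422) and Cdh15, M-cadherin, from 19.7 ± 3.85 to 37.8 ± 3.72 CPM (0.94, SE 0.14, adjusted p = 0.00240). The list held 8 rises adjusted over the list alone (camera adjusted p = 9.92e-05; adjusted p = 0.129 with an estimated correlation). Des (0.62, adjusted p = 0.0583) and Myf5 (0.87, adjusted p = 0.0958) did not pass over all genes. In the list of notch, Wnt and Hippo signalling, 3 of 16 genes rose over all genes and 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 4.12e-04; adjusted p = 0.129 with an estimated correlation), namely the receptors Notch1 (1.32) and Notch3 (1.14) and the notch target Heyl (0.94). The list of endothelium and mural cells held 5 rises among 15 members, 6 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.00158; adjusted p = 0.343 with an estimated correlation). The 5 were all genes of pericytes and smooth muscle: Myh11 (1.11), Notch3, Rgs5 (0.82), Kcnj8 (0.99) and Cspg4 (0.60). The endothelial marker Pecam1 stood at 2.38 ± 0.730 against 1.34 ± 0.477 CPM and did not pass (−0.83, adjusted p = 0.342).

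**Figure D2:**
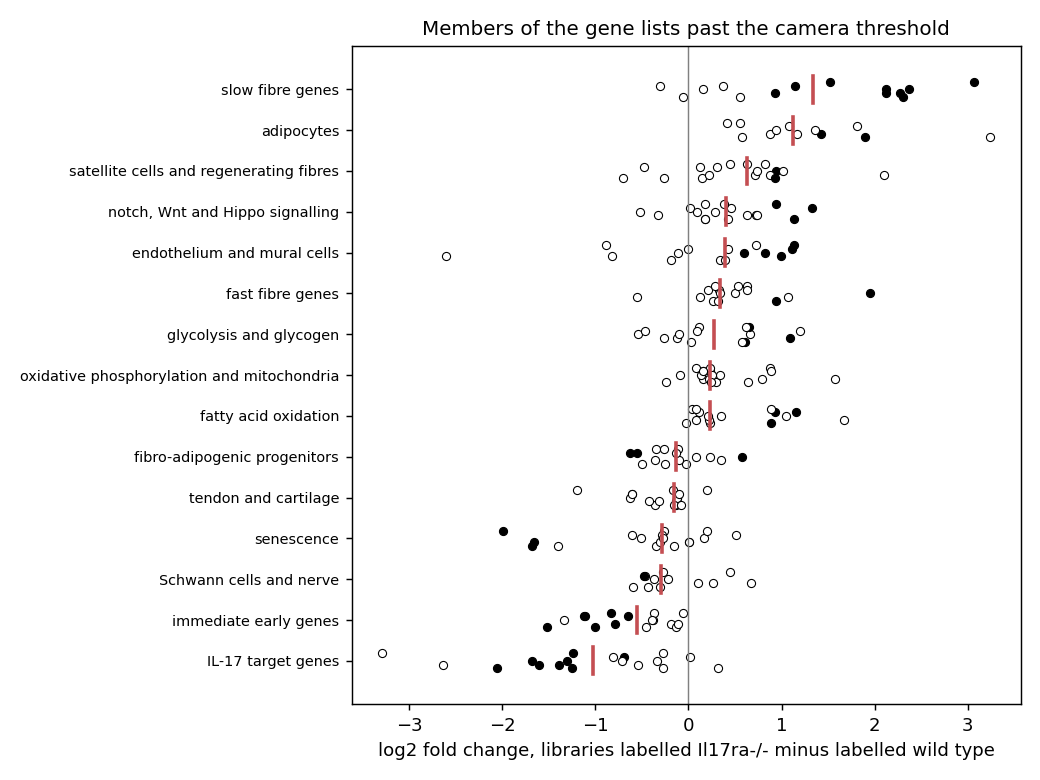
Log2 fold changes (x axis, labelled Il17ra-/- minus labelled wild type) of the tested members of the 15 gene lists past the camera threshold (y axis); filled points passed over all genes, open points did not, and the red bar is the median of the list. Slow fibre genes have the highest median, 1.33, and IL-17 target genes the lowest, −1.03.

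Some early response and IL-17 target genes fell in the libraries labelled Il17ra-/-, and none rose past the threshold. All 16 immediate early genes, which cells switch on within minutes of stress or stimulation, had a negative log2 fold change, and 7 fell over all genes and 10 adjusted over the list alone (camera adjusted p = 3.06e-11; adjusted p = 0.129 with an estimated correlation). Atf3 fell from 1677 ± 257 to 586 ± 201 CPM (−1.52, SE 0.23, adjusted p = 0.00193), Egr2 by 1.13, Fosl2 by 1.11 and Fosb by 0.79 on the log2 scale. The abundant early response genes Fos (6325 ± 434 against 5749 ± 415 CPM, −0.14, adjusted p = 0.524) and Egr1 (−0.38, adjusted p = 0.0610) did not pass. The list of IL-17 target genes holds chemokines, cytokines and feedback regulators induced by interleukin-17, many of which other inflammatory signals and stress induce too. Of its 18 tested members, 16 had a negative log2 fold change, and 8 fell over all genes and 10 adjusted over the list alone (camera adjusted p = 2.13e-08; adjusted p = 0.166 with an estimated correlation). Zc3h12a, which encodes the RNase regnase-1, fell from 42.0 ± 4.73 to 17.0 ± 2.61 CPM (−1.31, SE 0.14, adjusted p = 2.17e-04), and Nfkbiz, the regulator IκBζ, from 581 ± 63.3 to 222 ± 68.5 CPM (−1.39, SE 0.19, adjusted p = 0.00120). The chemokine genes Cxcl1 (−1.24) and Ccl7 (−1.61) fell as well. Both were highest in wild-type replicate 2. Over the 21 alternatives their smallest falls were −0.90 and −1.02, and both stayed called. Of 17 senescence genes, 3 fell, both over all genes and adjusted over the list alone (camera adjusted p = 2.67e-04; adjusted p = 0.260 with an estimated correlation). They included Cdkn1a, the cell cycle inhibitor p21, from 349 ± 59.3 to 110 ± 8.44 CPM (−1.66, SE 0.12, adjusted p = 2.16e-05), and Il6 (−1.68, SE 0.40, adjusted p = 0.0375), whose groups overlapped. Il6 also belongs to the acute stress response.

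Few fibroblast, tendon and nerve markers passed. Of 15 genes of fibro-adipogenic progenitors, the connective tissue cells of muscle, Pi16 (−0.55, adjusted p = 0.0207) and Cxcl14 (−0.62, adjusted p = 0.0237) fell and Hic1 (0.57, adjusted p = 0.0295) rose, with 2 rises and 4 falls adjusted over the list alone (camera adjusted p = 0.0387, lower; adjusted p = 0.468 with an estimated correlation). None of the 16 tendon and cartilage genes passed, over all genes or adjusted over the list alone (camera adjusted p = 0.0362, lower; adjusted p = 0.567 with an estimated correlation), and the smallest p belonged to Sox9 (−0.61, adjusted p = 0.102). Of 12 Schwann cell and nerve genes, the myelin gene Pmp22, which fibroblasts also express, fell (−0.48, adjusted p = 0.0229), with 1 rise and 4 falls adjusted over the list alone (camera adjusted p = 0.0362, lower; adjusted p = 0.468 with an estimated correlation). The means of these 3 lists per library had exact permutation p-values of 0.0635, 0.190 and 0.333. Their camera calls were lost in 3, 5 and 4 of the 9 fits that leave out 1 library (highest adjusted p = 0.144, 0.367 and 0.144). Of the 30 extracellular matrix and fibrosis genes, 1 fell, Ccn2, the connective tissue growth factor (−0.92, SE 0.19, adjusted p = 0.0150), over all genes and adjusted over the list alone, and the list did not pass (camera adjusted p = 0.685).

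**Figure D3:**
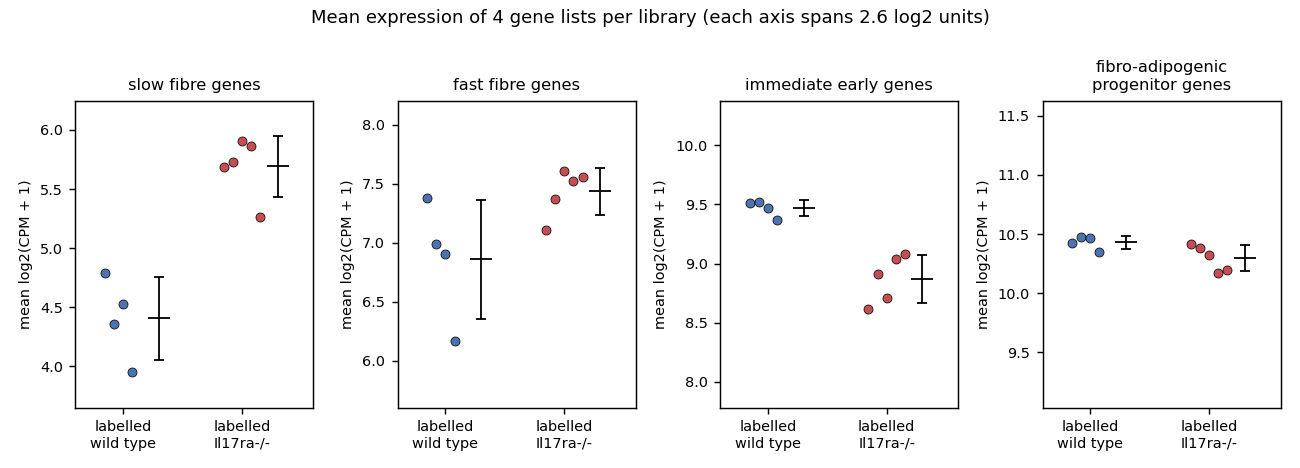
Mean log2(CPM + 1) of the slow fibre, fast fibre, immediate early and fibro-adipogenic progenitor lists (y axes, each of the same span) in each library (points) labelled wild type (blue, n = 4) or Il17ra-/- (red, n = 5), with the mean ± SD beside each group. The slow fibre and immediate early lists separate the groups, while the fast fibre and fibro-adipogenic lists overlap.

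The clock genes moved in opposite directions and the list did not pass the camera test (adjusted p = 0.320). Of 14 tested members, Nr1d1, Nr1d2 (1.48, adjusted p = 0.00125) and Dbp (1.68, adjusted p = 0.0135) rose and Per2 fell (−1.53, adjusted p = 0.00104), with 4 rises and 2 falls adjusted over the list alone. Fry's mixed test, which asks for change in either direction, gave an adjusted p of 2.08e-07, but it called 21 of the 27 lists. The labels tie no library to a day, so a difference in the time of collection cannot be separated from genotype for these genes. In the interferon list, Cxcl10 and Cxcl9 (−1.41, adjusted p = 0.0160) fell among 21 genes, with 1 rise and 3 falls adjusted over the list alone (camera adjusted p = 0.0964). In the list of atrophy and denervation genes, the metallothioneins Mt2 (−1.51, adjusted p = 0.00233) and Mt1 (−1.26, adjusted p = 0.00995), which bind metals and answer to stress hormones, fell and the ubiquitin ligase gene Fbxo32 (0.74, adjusted p = 0.0292) rose among 14, with 2 rises and 3 falls adjusted over the list alone (camera adjusted p = 0.669). Wild-type replicate 2 held the highest levels of Mt1 and Mt2. Their smallest falls over the 21 alternatives were −0.77 for Mt1 and −1.06 for Mt2, and both stayed called.

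Most immune cell markers were near the detection limit. None of the 14 neutrophil genes was abundant enough to be tested, and 8 had no count in any library. Of 12 tested macrophage genes Cd68 alone passed, over all genes and adjusted over the list alone (camera adjusted p = 0.669), while Lyz2 stood at 9.17 against 8.26 CPM. In the list of giant cells and lipid-handling macrophages, Cd36 rose among 10, also adjusted over the list alone (camera adjusted p = 0.968). No gene passed over all genes in the lists of alternative macrophage activation (10 tested, camera adjusted p = 0.968), antigen presentation (9 tested, 0.787), cell cycle (16 tested, 0.685), red cells (6 tested, 0.0964) and epidermis (5 tested, 0.669). Adjusted over the list alone, 1 cell cycle gene fell and none of the others in these lists passed. The IL-17 family list had a camera adjusted p of 0.185, with Il17ra and 1 more rise adjusted over the list alone. Only 4 T and NK cell genes, 4 B and plasma cell genes and 1 sex-linked gene, Xist (−0.41, adjusted p = 0.367), could be tested, so these lists have no camera test; none of these genes passed over all genes, and adjusted over the list alone 1 T and NK cell gene rose and 1 B and plasma cell gene fell. The median, mean and test of a list differed in sign for the clock (median −0.09, mean 0.28, tested higher), the giant cell (−0.08, −0.09, higher), the alternative activation (−0.03, 0.36, lower), the atrophy (0.07, −0.02, lower), the epidermis (−0.36, 0.06, lower) and the B and plasma cell (0.02, −0.01, no test) lists.

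In all, 15 of 27 lists passed the camera test, 9 higher and 6 lower, and 0 passed with an estimated correlation (5 had an unadjusted p under 0.05). An exact permutation test of the list means, chosen after the data were seen, called 0 lists: 8 reached the smallest p possible, 0.0159, which is an adjusted p of 0.0536 and 1 fewer than the 9 needed for any to pass, and 12 had an unadjusted p under 0.05. Fry called 10 lists in one direction.

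Library composition was compared over 18 measures, and 0 passed the adjustment in exact permutation tests (lowest adjusted p = 0.163). At least 6 measures would have had to reach the smallest p, 0.0159, for any to pass, and 3 had an unadjusted p under 0.05. These were the slow fibre (exact permutation p = 0.0159), fast fibre (p = 0.0476) and adipocyte lists, all higher in the libraries labelled Il17ra-/-. The mean of the fibro-adipogenic list differed by −0.13 on the log2 scale (exact permutation p = 0.0635) and that of the macrophage list by −0.05 (p = 0.603). The share of mitochondrially encoded transcripts was 1.40 ± 0.0832% against 1.57 ± 0.227% (exact permutation p = 0.222). The share of the mitochondrial ribosomal RNAs, chosen after its values were seen, was 0.139 ± 0.0201% against 0.0584 ± 0.0107% (exact permutation p = 0.0159).

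Called genes were not detectably concentrated around Il17ra. Of 208 tested genes within 10 Mb of it on chromosome 6, 11 were called, against 479 of 15830 elsewhere (odds ratio 1.79, 95% confidence interval 0.873 to 3.30, two-sided Fisher exact p = 0.0665). The 11 included the named genes Clec2e, from 129091998 to 129100913, and Timp4, from 115241892 to 115252205. The smallest p among them belonged to the tetraspanin gene Tspan11 (−1.28, adjusted p = 1.62e-04), named after its value was seen. The odds ratio was 0.933 without Il17ra-/- replicate 4, 1.04 without wild-type replicate 3 and 1.14 without Il17ra-/- replicate 3.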

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

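The tests of a single wrong label, of exchanged labels, of kept exons, of dilution by muscle fibre RNA, of scaling, of fewer macrophages and of the mitochondrial ribosomal RNA share were chosen after the results they bear on had been seen.

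Within groups, 22 of 294 sets of libraries held a library far from the others, where chance alone gives about 1 in 20, or 14.7. Wild-type replicate 2 accounted for 8 of them. It held the lowest share of counts in the 10 most abundant genes (10.9%, next 12.3%) and the lowest Traf6 (17.5 CPM, next 24.9), and the highest Atf3 (2059 CPM, next 1584), Mt1 (1201, next 509), Mt2 (638, next 307), Mfap5 (1391, next 933), Gadd45a (118, next 60.7) and Tmem88 (10.4, next 2.22). Wild-type replicate 4 had the lowest Cxcl14 (437 CPM, next 604) and Cox6a2 (6.80, next 19.3) and the highest Mcm6 (32.7, next 22.7) in its group, and wild-type replicate 3 was the only one of its group with a count of Tbx21 (0.168 CPM). Among the libraries labelled Il17ra-/-, replicate 5 had the highest mean log2(CPM + 1) of epidermis and hair genes (1.85, next 0.54), Dsp (7.78 CPM, next 0.532), Hbb-bt (13.9, next 7.89) and Mcm3 (17.3, next 11.7) and the lowest Tnnt1 (22.4, next 48.3). Replicate 1 had the lowest Dbp (9.41 CPM, next 12.2) and the highest Mgl2 (4.40, next 1.77) and Pax5 (3.28, next 0.596), replicate 2 the highest Adipoq (9.96, next 4.47) and replicate 4 the highest Il17ra (284, next 200 CPM, where the libraries labelled wild type reach 119).

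Il17ra was 2.15-fold higher in the libraries labelled Il17ra-/-, where a knockout of the whole gene would leave no transcript. A single wrong label is argued against if the level of Il17ra follows the genotype. The lowest library labelled Il17ra-/- was still 1.52 times the highest labelled wild type. An exchange of the labels between the groups stays open. The median of the IL-17 target list was −1.03, the direction of a loss of receptor under the labels as given. But the median of the immediate early list was negative too, and less stress in these libraries could lower the targets without the receptor. An allele that keeps transcribed exons also stays open, because counts are summed over the gene and the last exon alone holds 84.8% of the exon length. The knockout itself may raise transcription of such an allele, which was not tested.

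The immediate early and IL-17 target lists had negative median log2 fold changes, and both were called lower by camera with the preset correlation but not with an estimated one. Dilution by RNA of muscle fibres is argued against for the immediate early list. Its mean fell by 0.47 more on the log2 scale than that of fibro-adipogenic progenitors in the same libraries (a difference of −0.468, exact permutation p = 0.0159). For the IL-17 targets the difference was −0.605, with the groups less clearly apart (exact permutation p = 0.0476). The choice among the scalings run is argued against too. Over 4 other scalings the highest median log2 fold change was −0.485 for the immediate early list and −0.964 for the IL-17 targets. The larger range of a median over the scalings was 0.0723. A shift shared by all of these scalings would not be seen. Different handling of the tissue in the groups cannot be told apart from genotype: within groups the deviations of the 2 lists had a Pearson r of 0.493 over 9 libraries (exact permutation p = 0.139 over all 2880 rearrangements within groups), a Spearman rho of 0.467 (exact permutation p = 0.145) and an r of 0.322 without Il17ra-/- replicates 1 and 3, too few libraries to decide. The share of mitochondrial ribosomal RNAs also differed between the groups (0.139% against 0.0584%, exact permutation p = 0.0159), and the design does not separate preparation of the RNA from genotype there either. A loss of receptor signalling in the libraries labelled Il17ra-/- remains a candidate explanation for the targets, subject to the level of Il17ra itself.

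Cd68 had a log2 fold change of −2.80, and none of the 11 other tested genes of the macrophage list passed; Nrros, a gene of myeloid cells outside the list, fell too (−2.93). Fewer macrophages stay open. The median log2 fold change of the 5 other markers with a mean of at least 1 CPM was 0.179 (range −0.15 to 1.30), which is not the direction of a loss, and Lyz2 (−0.15, SE 0.23) and Cd14 (0.18, SE 0.28) did not pass. But only 3 of the 5 had a mean of at least 2 CPM, and other cells can express such genes. Of the 12 tested genes of the list, 4, Cd68 included, had negative values and 8 had positive ones. Genes near the detection limit went both ways. C1qb stood at −0.71 (SE 1.00) and C1qc at −0.68 (SE 1.09), but C1qa at 1.09 (SE 1.19) and Cd163 at 1.25 (SE 1.20). A hypothesis is that part of the Cd68 counts may be read-through from Eif4a1, which ends 783 bp upstream on the same strand and had a log2 fold change of −0.62 (adjusted p = 0.0823). Among genes under 20 CPM, 7 of 67 called lower had a gene at least 5 times as abundant within 5 kb upstream on the same strand. The 7 included mt-Nd3 of the mitochondrial genome. Among genes not called it was 523 of 8759 (odds ratio 1.84, 95% confidence interval 0.705 to 4.05, two-sided Fisher exact p = 0.121), which leaves read-through open. Among genes called higher it was 1 of 75, and this comparison was not tested. A difference between the genotypes in Cd68 itself was not tested apart from these.

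Of 100 splits of the 9 libraries into 4 and 5, the real one included, 1 gave as many as 491 called genes, the real one. The highest of the others was 135, with Il17ra-/- replicates 1 to 4 against the rest. This argues against a chance division of the libraries for the count of genes. For the gene lists 3 of 100 splits gave 15 or more, and the highest of the others was 16. Few splits reached the real number of lists, but not every possible split was run, so chance is not excluded for this number. Each of the 99 other splits called at least 1 list by camera, with a median of 7. A single list call with the preset correlation therefore carries little weight in these libraries.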

How the results depend on the processing

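The exact permutation test of list means was chosen after the data were seen; all other alternatives were fixed before. No gene among the 491 calls changed sign under any setting run. Il17ra stayed called higher under all 21 alternatives. Of 61 named genes that passed, 43 passed under all 21 alternatives, and Timp4 (13), Clec2e (11), Acsl1 (10), Adipoq (10) and Fabp3 (9) lost their call most often. Over all alternatives, 2470 of 2648 values of named genes kept their direction and side of the threshold, 117 lost the call and 61 gained one; 13 of the unchanged ones and 17 of those of lists changed sign without passing in either setting. For lists, 350 of 402 values kept their side, 37 lost the call and 15 gained one.

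The 491 calls (217 higher, 274 lower) became 1026 with DESeq2 (522, 504), 880 with limma-voom quality weights (410, 470), 827 at an adjusted p under 0.1 (399, 428) and 218 with an absolute log2 fold change of at least 1 (91, 127); the last 2 follow from their thresholds, and the cause of the others was not tested. Library totals alone gave 330 higher among 562, again without a tested cause. Leaving out 1 library gave 275 to 567 calls, 100 to 268 higher and 175 to 299 lower. The total was 275 (100, 175) without Il17ra-/- replicate 3 and 323 without replicate 1, and the higher calls were 122, 141 and 115 without Il17ra-/- replicates 1, 2 and 4 and 134 without wild-type replicate 4; these fits have fewer libraries. The log2 fold change of Il17ra ran from 0.97 to 1.23, and the number of lists called from 13 to 16. Leaving out 1 library ended the call of the tendon list in 5 of 9 fits, of the Schwann list in 4 and of the fibro-adipogenic list in 3, and that of no other list. The cause was not tested. The list count was 0 with an estimated correlation, for which the cause was not tested, and 0 by exact permutation of list means, where 8 lists reached the smallest p and 9 were needed. The odds ratio around Il17ra ran from 0.933 to 1.89, and 0.933 (Fisher exact p = 1), without Il17ra-/- replicate 4, lies on the other side of 1; the cause was not tested. It was 1.10 within 5 Mb and 1.38 within 20 Mb. The composition tests say nothing about stability, since 6 of 18 measures would have to reach the smallest exact p together for any to pass.

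The replicate numbers gave no clear sign of pairing, which 4 pairs are too few to exclude. Deviations of same-numbered libraries correlated at −0.0174 to 0.0557 over 4 pairs, and 2 of 4 libraries labelled wild type correlated best with their own number. With the replicate number as a block, over 8 libraries, 366 genes were called, 140 higher and 226 lower, 325 of them among the 491, Il17ra had a log2 fold change of 1.14 and 14 lists passed. That fit leaves out Il17ra-/- replicate 5, and without this library and without the block 417 genes (173 higher, 244 lower) and 13 lists passed; the calls of the Schwann and fibro-adipogenic lists were lost in both fits, so their loss is not put down to the block. At this depth and number of libraries the simulated recovery of 1.5-fold changes was 19.4%, so a gene that did not pass is not shown to be unchanged.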

Other observations

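The gene families below, the genes named in this part and the test of each family were chosen after the values were seen. Each family is tested on the same calls, so the p-values only describe the counts and are no evidence for a family. Chaperone genes were called more often than other genes. Of 68 tested heat shock and DnaJ genes, 12 were lower and 2 higher in the libraries labelled Il17ra-/- (odds ratio 8.42, two-sided Fisher exact p = 1.43e-08, adjusted over 9 families p = 1.29e-07). Genes are not independent replicates. The median log2 fold change of this family was −0.07, against −0.003 for all tested genes. The falls included Dnajb1 from 330 to 108 CPM (−1.61, SE 0.15, adjusted p = 1.11e-04), Hspa5, the chaperone BiP of the endoplasmic reticulum, from 2269 to 1156 CPM (−0.97, SE 0.15, adjusted p = 0.00208), Hspa8 (−0.83), Hsp90aa1 (−0.94), Hsph1 (−1.06) and the stress-inducible pair Hspa1a (−0.99) and Hspa1b (−1.04), near-identical copies whose counts are uncertain. The rises were the small heat shock proteins of muscle, Hspb7 (1.41, adjusted p = 0.00515) and Hspb6 (1.11, adjusted p = 0.0423). Chemokine genes showed 7 falls and no rise among 18 tested (odds ratio 20.4, adjusted p = 2.58e-06 by Fisher's exact test over the families), and several of them belong to the IL-17 target list. No collagen gene of 44, no cytosolic ribosomal protein gene of 80 and no nuclear NADH dehydrogenase gene of 46 was called. Further genes with small p-values were the interferon regulatory factor Irf1, which fell from 650 ± 181 to 175 ± 35.7 CPM (−1.89, SE 0.18, adjusted p = 1.50e-04), the adhesion molecule gene Icam1 (−1.39, SE 0.12, adjusted p = 1.10e-04) and the NF-κB inhibitor Nfkbia (−1.35, SE 0.15, adjusted p = 2.80e-04).

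Mitochondrial transcripts differed between the groups in an uneven way. The mitochondrial ribosomal RNAs mt-Rnr1 (−1.26, SE 0.13, adjusted p = 1.62e-04) and mt-Rnr2 (−1.35, SE 0.15, adjusted p = 2.42e-04) were lower in every library labelled Il17ra-/-, and their share of counts was 0.139 ± 0.0201% (n = 4) against 0.0584 ± 0.0107% (n = 5, exact permutation p = 0.0159). mt-Nd3, which encodes a subunit of respiratory complex I, had 43, 46, 56 and 50 counts in the libraries labelled wild type and 0, 0, 0, 0 and 1 in those labelled Il17ra-/- (edgeR adjusted p = 7.93e-04), while the 7 other mitochondrial protein genes tested had log2 fold changes between 0.03 and 0.58. Whether mt-Nd3 differs in expression, or in a mitochondrial sequence that changes where reads map, is not settled by counts, and reads were not analysed here. Mid1-ps1, a pseudogene listed on chromosome Y whose reads can be shared with Mid1, had 3, 0, 2 and 0 counts against 61, 25, 39, 37 and 63. Other chromosome Y genes do not show a difference of sex between the groups. Ddx3y, Uty and Eif2s3y had no count in any library and Kdm5d reached at most 0.0279 CPM. Xist stood at 195 to 503 CPM. Gm10925, a gene model on chromosome 1 from 24613974 to 24614651, had 34 counts in Il17ra-/- replicate 5 and 395 to 618 in the other 8 libraries, and its neighbours Gm29216, Gm28437 and Gm28661 had 24, 33 and 41 counts there against at least 315 elsewhere; here too counts do not separate expression from sequence. Gt(ROSA)26Sor, on chromosome 6 from 113067428 to 113077333, stood at 10.9 ± 1.55 against 4.54 ± 1.15 CPM (−1.26, SE 0.22, adjusted p = 0.00516).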
